A study of Homo sapiens with 6 samples.

How the data were processed

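Total RNA from UMUC3-c31 cells, a line named for the human bladder carcinoma line UMUC3, was biotin-labelled and hybridised to 6 Affymetrix arrays, 1 per sample. Per the labels' protocols, the cells were kept for 24 h in serum stripped with charcoal, which removes steroid hormones. They were then treated for 24 h with ethanol vehicle or with 10 nM R1881, a synthetic androgen. The design text gives 3 biological replicates per condition. How c31 was derived is not given in the sources used here.

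The deposited table holds 1 value per probe set and array on the log2 scale, made by the authors with RMA, per the submitters' processing notes. RMA corrects background, quantile-normalizes between arrays and summarises the probes of a set, so that a change of the whole transcriptome in one direction would be removed. The version and any filter are not given in the sources used here. The deposited log2 values are rounded to 2 decimals, which sets the finest difference they can show. The array medians were 5.49 to 5.51 over 49193 probe sets. Scanner files and detection calls were not used here, so signal over background is known only through a proxy. The precision of every value is limited by 3 arrays per group.

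Probe sets were named through the platform's annotation table. Of the 49193 probe sets, 44898 had 1 gene symbol, 1825 had several and 2470 were not listed with a gene. The Entrez identifiers of 44871 probe sets were found in a RefSeq gene table, and no symbol needed an update. Only probe sets with 1 symbol entered the tests, and a gene with several was represented by the one with the highest mean over all 6 arrays. This gave 18129 genes, of which 11714 had more than 1 probe set. No coordinates are given, since the values carry no genome build. Level differences between probe sets reflect probe affinity as well as RNA, so genes were compared only with themselves. Sets whose identifiers carry an s or x before "_at" hold probes that match several transcripts, so signal of close relatives can mix there. Of the 97 genes named or eligible for naming below, 38 were on such sets, among them 4 of the 21 made up of CD44 and the largest changes. One planned gene result is not reported here.

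R1881 was compared with vehicle in a linear model with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and no trend (lmFit, eBayes). No pseudocount or filter was used. P-values are two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. An adjusted p below refers to this test unless a list is named. Changes are given as log2 of R1881 minus vehicle with the standard error (SE) of the moderated fit, and n = 3 arrays per group throughout. Olfactory receptor and keratin-associated protein genes (423 genes) served as a proxy for background. The 90th percentile of their means, 4.99 on the log2 scale, was taken as the background level. Where 1 group of a named gene lay below it, the fold is given as at least that of the other group's mean over this level, and none is given where both did. In all, 11049 genes lay above it in at least 1 group.

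There were 32 gene lists, written from general knowledge, of which 861 of 937 memberships were measured. Each list was tested with limma's camera, which asks whether its members changed more than other genes, with a preset correlation between genes of 0.01 and adjustment over the 32 lists. Camera with an estimated correlation, and fry, which tests whether a list's genes move on balance one way, were alternatives. The lists overlap, and a gene in several is counted in each. Named genes were CD44, the 10 largest rises and the 10 largest falls among changed genes above background whose arrays did not overlap between groups, and up to 4 members with the smallest p of each list described. Symbols of unnamed loci, microRNAs, small RNAs and antisense genes were left out of that rule. Where a count was 5 or fewer, members outside the rule are named too, and these were chosen after their values were seen. The lists, the rule, the main tests and the alternatives given below were fixed before the data were examined, and tests or fits added later are named where they are reported.

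On simulated arrays with the spread of the R1881 comparison over 18129 genes, the fit recovered 54% of genes changed by 0.3 on the log2 scale, 98% at 0.5 and 100% at 1. Of the genes it called, 4.35% had not been changed. The simulated noise was independent between genes and drawn from the fit's own spread, and the changed genes all lay above background. These shares need not hold on real arrays. Replicate numbers run from 1 to 3 in both groups. The alternatives were re-centred or re-normalized arrays, a filter on dim genes, other prior variances, array weights, a replicate block, other rules for several probe sets and leaving out each array in turn. No 2 arrays were alike: at most 9.02% of probe sets had equal values in a pair.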

Results

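Gene expression was measured on arrays in UMUC3-c31 bladder cancer cells after 24 h with 10 nM R1881 or with ethanol vehicle, 3 arrays each. CD44, a cell-surface receptor for hyaluronan, is among the genes the series title names, and the comparison asks which transcripts respond to the androgen. The groups separated on the first principal component, which held 43.2% of the variance over genes. The vehicle arrays scored between -14.0 and -7.24 on it and the R1881 arrays between 9.41 and 10.2. Vehicle replicate 1 lay apart from the other vehicle arrays on the second component (11.04 against -8.21 and -6.99), which held 19.6% of the variance.

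CD44 transcript was lower with R1881. On its brightest probe set it went from 12.60 ± 0.07 (SD, n = 3) to 12.32 ± 0.04 (SD, n = 3), a log2 change of -0.28 ± 0.05 (SE), or 0.824 times the vehicle level with a 95% confidence interval of 0.756 to 0.898. The brightest set lay above 12 on the log2 scale, where arrays may compress changes (not tested here), and had the smallest fall of the 10. All 10 CD44 probe sets were lower with R1881, by -0.28 to -0.40 with a median of -0.37, and 8 of them passed the threshold when every probe set was tested. The groups did not overlap on the brightest set, and an exact two-sided permutation test gave p = 0.10, the smallest that 3 against 3 allows. The limma adjusted p of 0.0468 lay close to the threshold. It rose to between 0.0530 and 0.163 when any 1 of the 6 arrays was left out, to 0.0702 when every probe set was tested and to 0.0561 after another quantile normalization, while the mean over the 10 probe sets fell by 0.36 with an adjusted p of 0.00384.

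**Figure D1:**
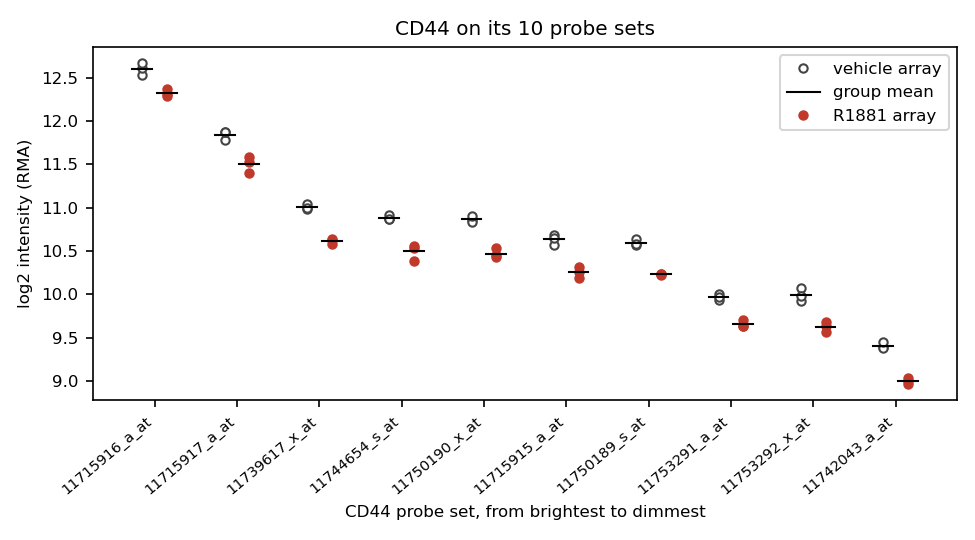
Log2 RMA intensity (y axis) of the 10 CD44 probe sets (x axis, brightest first) on each vehicle array (open points) and R1881 array (filled points), with lines at the group means. Every probe set has its R1881 mean below its vehicle mean, by 0.28 to 0.40.

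R1881 changed 438 of the 18129 genes tested, raising 290 and lowering 148. The balance depended on the fit, with 475 higher and 420 lower under a trended, robust prior and 418 and 337 without dim genes. The rises were also larger: 114 genes rose and 19 fell by at least 1.5-fold, and 26 rose and 1 fell by at least 2-fold. The largest rise was in EDN2, which encodes the vasoconstrictor peptide endothelin 2 and went up by 2.61 ± 0.09 (SE), or 6.12-fold. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose by 2.52 ± 0.07, and NSG1, a protein of the endosomal pathway, rose at least 3.91-fold, from a measured 4.45, below the background level, to 6.96. CRISPLD2, a secreted glycoprotein, rose by 2.41 ± 0.06, or 5.30-fold. PXYLP1, a phosphatase of proteoglycan linker synthesis, rose by 1.93 ± 0.06. The angiogenic growth factor gene PGF rose by 1.86 ± 0.08 and DEPP1, a target of FOXO factors, by 1.79 ± 0.08. KANK1, a regulator of actin and adhesion, rose by 1.59 ± 0.07. SNAI2, the transcription factor Slug, rose by 1.53 ± 0.06, and the kinase gene RIPK4 by 1.5 ± 0.07. The adjusted p of these 10 genes ran from 1.50e-05 to 1.70e-04, and each kept its call when any 1 array was left out.

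Falls were led by NTS, which encodes the peptide neurotensin and fell at least 2.84-fold, to a measured 4.66, below the background level. No other fall reached 2-fold. IFIT1 and IFIT2, interferon-induced antiviral genes, fell by 0.87 ± 0.12 and 0.83 ± 0.05, and the matrix glycoprotein gene TNC by 0.87 ± 0.07. CLGN, a chaperone of the endoplasmic reticulum, fell by 0.82 ± 0.09. HBEGF, a ligand of the epidermal growth factor receptor, fell by 0.82 ± 0.04, and the transcription factor gene KLF2 by 0.78 ± 0.05. ADTRP fell by 0.76 ± 0.07, NTN4, a secreted netrin, by 0.75 ± 0.07, and EVI2A by 0.70 ± 0.08. Of these 10 genes only IFIT1 lost its call in a leave-out, with an adjusted p of up to 0.0769 without vehicle replicate 1 or without vehicle replicate 2. Every gene called had non-overlapping groups, as had 18.5% of all genes, where chance gives 10%. Without any 1 array the count of changed genes was 209 to 270, and it was 270 without vehicle replicate 1, 243 without vehicle replicate 2, 223 without vehicle replicate 3, and 225, 209 and 226 without R1881 replicates 1, 2 and 3.

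**Figure D2:**
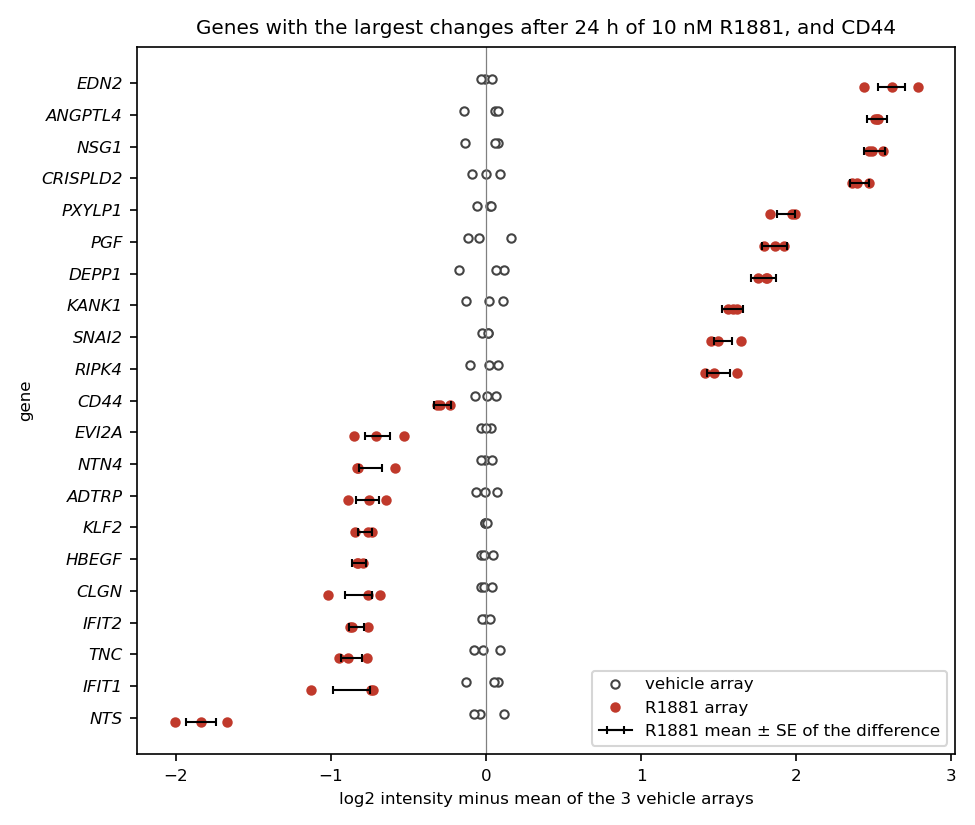
Log2 intensity of each array minus the mean of the 3 vehicle arrays (x axis) for CD44 and the 10 largest rises and falls (y axis). Open points are vehicle arrays, filled points R1881 arrays and bars the R1881 mean ± SE of the difference. EDN2 stands highest at 2.61 and CD44 at -0.28. NTS stands lowest, at a measured -1.84, and its R1881 arrays and the vehicle arrays of NSG1 average below the background level.

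Of the 91 measured members of the androgen response list, genes that androgen induces in prostate cells, 8 rose, 2 fell and 81 did not pass the threshold (10 higher and 3 lower when adjusted over the list alone). FKBP5, a cochaperone of steroid receptors and a common androgen target, rose by 1.49 ± 0.05, NDRG1 by 0.90 ± 0.06, the fatty acid desaturase gene FADS1 by 0.82 ± 0.05 and the sulphate transporter gene SLC26A2 by 0.35 ± 0.05. The 2 genes that fell were ARID5B (-0.59 ± 0.09) and ADAMTS1 (-0.28 ± 0.05). Among 28 measured members of the shorter list of core prostate androgen-induced genes, 3 rose, namely FKBP5, NDRG1 and ELL2 (0.27 ± 0.04), none fell and 25 did not pass, FOXP1 among them at -0.21 ± 0.05 with an adjusted p of 0.0803. Adjusted over the list alone, 3 were higher and 1 lower. Above background lay 18 of these 28, and 78 of the 91 androgen response members. Neither list moved apart from other genes by camera (adjusted p = 0.205 for androgen response, with a median of 0.01, and 0.310 for the core list, with a median of 0.04). Both passed fry (adjusted p = 0.00163 and 8.80e-05), which does not compare a list with other genes. With every probe set tested the androgen response list passed camera (adjusted p = 0.00247), as it did with the mean of a gene's probe sets (0.0294). In the former a gene counts once for each of its probe sets (FKBP5 and NDRG1 have 6 each). The members are then less independent than the preset correlation assumes. SLC26A2 lost its call without vehicle replicate 2, R1881 replicate 1 or R1881 replicate 2 (adjusted p up to 0.0679), ELL2 and ADAMTS1 without any 1 of the 6 arrays (up to 0.136), and ARID5B without any array but R1881 replicate 1 (up to 0.102).

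Of 24 measured glucocorticoid-induced genes, many of which respond to several steroid receptors, 11 rose, none fell and 13 did not pass, and 14 were higher when adjusted over the list alone. CRISPLD2, ANGPTL4 and FKBP5 led the list, followed by the phosphatase gene DUSP1, which rose by 0.74 ± 0.04. The list's median was 0.28 and it stood apart from other genes (camera adjusted p = 1.11e-16, and 0.0190 with an estimated correlation). NR3C1, the glucocorticoid receptor gene, rose by 0.25 ± 0.05 (adjusted p = 0.0462) and was the only called member among 17 measured steroid receptors and cofactors (camera adjusted p = 0.735). It lost its call without any 1 of the 6 arrays (adjusted p up to 0.148).

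Of 27 measured hypoxia and glycolysis genes 8 rose, none fell and 19 did not pass, with 16 higher when adjusted over the list alone. The list's median was 0.16 and its camera adjusted p was 5.62e-12, but adjusted p = 0.126 with an estimated correlation. Besides ANGPTL4 and NDRG1, the angiogenic factor gene VEGFA rose by 1.15 ± 0.07, or 2.22-fold, and the vasodilator peptide gene ADM by 0.61 ± 0.05.

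Of 40 S phase genes 6 fell, none rose and 34 did not pass over all genes, and 30 were lower when adjusted over the list alone. The transcription factor gene E2F8 fell by 0.38 ± 0.07, the recombination factor gene RAD51AP1 by 0.30 ± 0.05, the primase gene PRIM1 by 0.26 ± 0.04 and GINS2, part of the replicative helicase, by 0.25 ± 0.04. Of 51 G2/M genes 2 fell, the kinesin gene KIF23 by 0.32 ± 0.06 and the kinetochore gene NUF2 by 0.30 ± 0.06, and 49 did not pass, with 20 lower when adjusted over the list alone. ECT2 stood at -0.23 ± 0.05 and the survivin gene BIRC5 at -0.20 ± 0.04, with adjusted p of 0.0560 and 0.0647. The medians were -0.16 for S phase and -0.13 for G2/M. Camera gave adjusted p of 1.99e-19 and 8.79e-12, and 0.0215 and 0.0190 with an estimated correlation. CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 0.42 ± 0.05 (adjusted p = 0.00492). The single-gene calls were fragile: E2F8, PRIM1, GINS2, KIF23 and NUF2 lost theirs without any 1 of the 6 arrays (adjusted p of 0.0650 to 0.164), and RAD51AP1 without any array but vehicle replicate 2 (up to 0.131). With 1 array fewer the calls over all genes also dropped, from 438 to between 209 and 270, so these losses point to no single array.

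Of 24 measured NF-kB and cytokine genes 6 rose, 1 fell (CXCL3, -0.40 ± 0.07) and 17 did not pass, and 8 were higher and 1 lower when adjusted over the list alone. TNFAIP3, the A20 inhibitor of NF-kB signalling, rose by 1.32 ± 0.06, IER3 by 0.73 ± 0.04, the inhibitor gene NFKBIA by 0.41 ± 0.05 and the chemokine gene CCL2 by 0.39 ± 0.05. TNFAIP3 and NFKBIA restrain NF-kB, but the 6 genes that rose also included chemokine genes, CCL2 among them. The list's camera adjusted p was 7.02e-04, but adjusted p = 0.286 with an estimated correlation. Of 30 measured interferon response genes 5 fell (IFIT1, IFIT2, OASL, IFI44 and IFIT3), none rose and 25 did not pass, while adjusted over the list alone 6 were lower and 3 higher. OASL fell by 0.46 ± 0.06, IFI44 by 0.37 ± 0.07 and IFIT3 by 0.42 ± 0.08. The list as a whole did not stand apart (camera adjusted p = 0.726), and its median of 0.01 and mean of -0.06 differed in sign. CCL2 lost its call without vehicle replicate 3 (adjusted p = 0.0501), IFI44 and CXCL3 without any 1 array (up to 0.145), and IFIT3 without any array but R1881 replicate 2 (up to 0.173).

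Of 47 measured genes of epithelial-mesenchymal transition, 8 rose, 1 fell (TNC) and 38 did not pass, with 13 higher and 4 lower when adjusted over the list alone. SNAI2 led the rises, with IGFBP3, a carrier of insulin-like growth factors, at 1.0 ± 0.07 and the fibronectin gene FN1 at 0.73 ± 0.08. The camera adjusted p was 0.0259, but adjusted p = 0.384 with an estimated correlation, and it was 0.112 without R1881 replicate 1 and 0.0608 without R1881 replicate 2. Of 26 immediate early and ERK feedback genes 4 fell, 1 rose (IER3) and 21 did not pass, with 10 lower and 4 higher when adjusted over the list alone. Those that fell were HBEGF, EREG (-0.68 ± 0.07), IER2 (-0.40 ± 0.04) and DUSP4 (-0.27 ± 0.04). Its camera adjusted p was 0.0145, but adjusted p = 0.379 with an estimated correlation, and it was 0.0860 without vehicle replicate 2 and 0.112 without R1881 replicate 1. DUSP4 lost its call without any 1 of the 6 arrays (adjusted p up to 0.120).

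Among 27 measured genes of the CD44 and hyaluronan axis, 2 rose, 2 fell and 23 did not pass, and the counts were alike when adjusted over the list alone, 2 and 2. The hyaluronan synthase genes went opposite ways, HAS3 up by 0.64 ± 0.07 and HAS2 down by 0.41 ± 0.05. ANK3 rose by 0.33 ± 0.05. CD44 was the other gene that fell. Of 21 measured cancer stem cell markers 2 fell, CD44 and the integrin gene ITGA6 (-0.41 ± 0.06), none rose and 19 did not pass. Values that did not pass there were -0.25 ± 0.06 for EZH2 and 0.24 ± 0.07 for THY1. Adjusted over the list alone, 3 stem cell markers were lower and none higher. Camera adjusted p were 0.814 for the hyaluronan axis and 0.726 for the stem cell markers. HAS2 lost its call without R1881 replicate 1 or 3 (adjusted p up to 0.0603), ANK3 without any array but vehicle replicate 1 (up to 0.0844), and ITGA6 likewise (up to 0.0868).

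**Figure D3:**
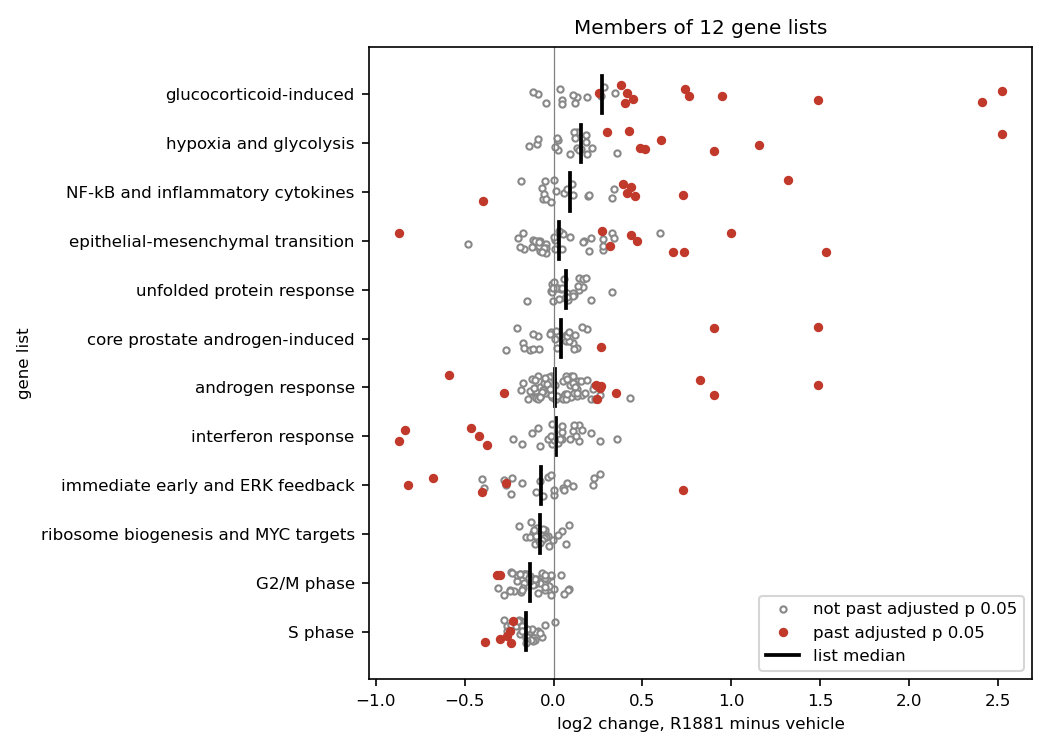
Log2 change, R1881 minus vehicle (x axis), of each measured member of 12 gene lists (y axis). Filled points passed an adjusted p of 0.05, open points did not, and bars mark list medians, from 0.28 for glucocorticoid-induced genes to -0.16 for S phase genes.

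In 2 further lists every measured member stayed under the threshold, over all genes and adjusted over the list alone, although camera set the list apart. The camera adjusted p was 9.37e-04 for both, but adjusted p = 0.286 for both with an estimated correlation. By limma, 10 unfolded protein response and 3 ribosome biogenesis genes had an unadjusted p under 0.05. Unfolded protein response genes had a median of 0.07, with 22 of 28 higher by sign and the chaperone gene DNAJC3 at 0.21 ± 0.05. Ribosome biogenesis and MYC targets had a median of -0.07, with 4 of 29 higher by sign and POLR1B at -0.19 ± 0.08. Markers of cell types not present in a pure culture gave 1 call: among 20 immune and endothelial markers the angiopoietin receptor gene TEK was called, with a measured 3.72 ± 0.19 and 5.0 ± 0.26 (SD), below and at the background level, and none of 17 fibroblast markers was called by limma (3 at an unadjusted p under 0.05, and 1 higher and 1 lower adjusted over the list alone). Camera adjusted p were 0.735 and 0.904. Only 6 of the 20 and 8 of the 17 lay above background in at least 1 group.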

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

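The tests on oxygen, dim members, shared list members and lists without 1 array were chosen only after the lists' results were seen. The middle range in the oxygen test was added after its first interval was seen. That interval (0.02 to 0.16) lay under the test's bound of 0.25, but wholly on the side of a rise. By itself it could thus not have excluded a smaller effect of lower oxygen. The probe sets left out of the comparison for want of a single gene name also held a response. Of 1825 probe sets with several gene symbols 15 passed the threshold when all 49193 were tested with limma, 10 higher and 5 lower with R1881. Of 2470 not listed with a gene 38 passed, 37 higher and 1 lower, with a largest rise of 1.69. These shares, 0.822% and 1.54%, stand beside 1.57% of the probe sets with 1 gene.

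A first pattern is the higher hypoxia and glycolysis list by camera. Removing the 3 members shared with the steroid-induced lists left 24 genes with 6 calls and a camera p of 2.93e-09, or 2.34e-08 adjusted over the lists, which argues against those members as the whole of it. With an estimated correlation neither the full list (adjusted p = 0.126) nor the reduced one (adjusted p = 0.160) passed. Lower oxygen in the treated wells would raise oxygen-regulated genes, here those taken to lack steroid control, which was not tested. Over 13 such genes the median was 0.12 with a bootstrap interval of 0.02 to 0.16, and 12 were higher by sign. ANKRD37 stood highest (0.36 ± 0.07), while BNIP3, PGAM1 and ENO1 hardly moved (0.01, 0.02 and 0.02). EGLN3 lay below background, and PDK1 stood at -0.14 ± 0.06 (limma, unadjusted p = 0.0440). All 13 belong to the hypoxia list itself and were picked after its results were seen. The list's 8 called members are not among them, so the absence of calls follows from that choice. Of the 13, 6 lay above 12 on the log2 scale, where arrays may compress changes, which was not tested. The 6 in the middle range gave an interval of -0.01 to 0.27. Both intervals came from resampling genes, which are not independent, and leave out the error between arrays. Lower oxygen therefore cannot be told apart from an effect of R1881. A rise of EPAS1, the gene of a hypoxia-inducible factor, by 1.40 ± 0.06 is an untested biological alternative.

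A second pattern is the lower S phase list by camera. Their median of -0.16 was below that of every one of 10000 random lists matched on intensity (0% as low, the lowest at -0.085), which argues against an intensity-dependent bias. The direction and the call held in 6 of 6 leave-outs (largest adjusted p 6.16e-17), which argues against a single array as the cause. At the preset correlation used there, however, another split of the 6 arrays gave a camera p of 9.34e-06 for the list (real split 6.21e-21). With an estimated correlation the real split gave a camera p of 0.00202 and the smallest of the others was 0.389. Slower division under R1881, and a difference in cell density between wells, stay open as untested explanations.

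The last pattern is that glucocorticoid-induced genes rose more often than the androgen response list. Among members above background and in only 1 of the lists, 10 of 15 and 7 of 76 rose (two-sided Fisher's exact test, p = 5.98e-06, over genes, which are not independent). The androgen response list was the less dim of the 2, with 78 of 91 measured members above background against 17 of 24. Leaving dim members out could thus hardly narrow the gap. These counts, rather than the test, argue against dim androgen targets as the cause. Which receptor carried the response, and whether genes chosen in prostate cells fit a bladder line, were not tested and stay open.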

How the results depend on the processing

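Changed, higher and lower genes numbered 438, 290 and 148, and no gene called there reversed in any alternative fit. Leaving out dim genes gave 755 changed and 337 lower genes, and a trended, robust prior gave 895, 475 and 420. Requiring 1.5-fold gave 133, 114 and 19. The design text gives no pairing by replicate number, and the values leave it open. Same-numbered deviations correlated at only 0.09, 0.06 and 0.03, yet every array matched its own number best, which is only a hint from the data. The replicate block gave 222, 170 and 52 genes and CD44 at -0.28 with an adjusted p of 0.128. Leaving out 1 array gave 209 to 270, 152 to 198 and 53 to 72 genes, with smaller groups, and CD44 at -0.32 to -0.25. CD44 also missed the threshold after quantile normalization (-0.27) and with every probe set tested (-0.28), and kept the call with means of probe sets, a trended, robust prior, array weights, median-centring and without dim genes (adjusted p of 0.00203 to 0.0405). The androgen response list, with a mean of 0.0599, passed by fry (0.0599, adjusted p = 0.00163) and with means of probe sets (0.0620). It also passed with every probe set (0.0761), where a gene counts once for each of its sets. The cause of these shifts was not tested. Of 77 called genes named here or eligible for naming, 43 kept the call in all leave-outs, and no named gene changed direction. Leaving out arrays was tried for the lists described, apart from androgen response, only after their results were seen, as was the count of genes over splits. The immune and endothelial list turned direction by camera without vehicle replicate 2 (mean 0.0432, adjusted p = 0.855; the means were 0.0432 to 0.0847 over the leave-outs). With an estimated correlation 3 of 32 lists passed rather than 9 (fry: 15, those 9 and the androgen response, core prostate androgen-induced, androgen-repressed, luminal, polyamine and histone lists). With 10 splits of 6 arrays, no share can fall under 0.05: the real split (1 of 10 as large) called 438 genes against 0 at most in the others, 9 lists against 6 (3 against 0 with an estimated correlation), and an androgen response camera p of 0.0770 against 0.240 (1 of 10 each). Another split gave a smaller camera p than the real one for immediate early genes (9.42e-04 against 0.00362, and 0.0333 against 0.130 with an estimated correlation). For epithelial-mesenchymal transition this held only with an estimated correlation (0.0466 against 0.144).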

Other observations

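The EGFR ligand test was chosen only after the result was seen. Of 28 measured luminal urothelial markers 1 fell, the keratin gene KRT18 by 0.37 ± 0.05, and 1 rose, KRT7 by 0.40 ± 0.06. The 21 basal and squamous markers held 2 calls, the falls of ITGA6 and CD44, and LAMB3 stood at -0.29 ± 0.07 with an adjusted p of 0.110. Only 6 of these 21 and 13 of the 28 luminal markers lay above background. Among 25 p53 targets CDKN1A (0.42 ± 0.05), GADD45A (0.26 ± 0.04) and SESN1 (0.27 ± 0.05) rose and none fell, and the list's median of -0.003 and mean of 0.02 differed in sign. Of 19 TGF-beta targets the activin subunit gene INHBA rose by 0.67 ± 0.09, and ID3, ID1 and TGIF1 fell by 0.35 ± 0.05, 0.25 ± 0.04 and 0.28 ± 0.04. None of these 4 lists passed camera (adjusted p of 0.144, 0.330, 0.735 and 0.735), while the luminal list passed fry (adjusted p = 0.00923). GADD45A, SESN1, ID1 and TGIF1 lost their calls without any 1 array (adjusted p of up to 0.159), KRT7 and INHBA without any array but R1881 replicate 3, and ID3 without any array but R1881 replicate 1 (up to 0.104).

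No member passed an adjusted p of 0.05 among 37 oxidative phosphorylation, 19 cholesterol synthesis, 23 steroid and glucuronide metabolism, 17 neuroendocrine or 18 polyamine and secretory genes by limma. At an unadjusted p under 0.05 these held 1, 1, 1, 2 and 4 genes, and adjusted over the list alone 1 neuroendocrine gene was higher. Their camera adjusted p were 0.186 to 0.761. Only 4 of the 23 steroid and glucuronide genes and 8 of the 17 neuroendocrine genes lay above background. The others could not show a fall. Of 18 measured genes that androgen represses in prostate cells, 1 was called, a rise of CAMK2N1 by 0.52 ± 0.05. Only 7 of the 18 lay above background, so the others could not show a fall. Of 14 prostate epithelial markers STEAP1 was called, with a fall of 0.42 ± 0.06. Wnt targets (17 measured) held a rise of DKK1 by 0.41 ± 0.06, the fall of CD44 and a call of AXIN2, whose level lay below background in both groups. The 18 fatty acid synthesis genes held the rise of FADS1 and a fall of ELOVL6 by 0.29 ± 0.05. Among 20 heat shock and oxidative stress genes BAG3 rose by 0.45 ± 0.04, MT1X by 0.95 ± 0.12 and HMOX1 fell by 0.44 ± 0.04, and the list's median of -0.04 and mean of 0.02 differed in sign. Among 20 replication-dependent histone genes H4C8 rose at least 1.90-fold, from a vehicle level below background. H1-4 fell at least 1.22-fold, to an R1881 level below background. MT1X and H4C8 have close relatives whose signal their probes could not be shown to exclude. None of these 6 lists passed camera (adjusted p of 0.488 to 0.761), and these members were chosen after their values were seen. ELOVL6 and H1-4 lost their calls without any 1 array, AXIN2 without any array but R1881 replicate 3, DKK1 without any array but vehicle replicate 1, and STEAP1 and MT1X without vehicle replicate 3 or any R1881 array (adjusted p of up to 0.179).

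HBEGF and EREG fell, which raised the question whether ligands of the epidermal growth factor receptor fell as a set. The 6 measured ligands gave a camera p of 0.247 (0.352 with an estimated correlation), but 3 of them lay below background and could not show a fall, so the set test leaves this open. Of the 3 above background, HBEGF and EREG fell and TGFA rose by 0.66 ± 0.06.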
